A study of Mus musculus and Drosophila melanogaster with 49 samples.

How the data were processed

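Small RNA was sequenced from sorted mouse crypt cells and from fly midguts, messenger RNA from sorted crypt cells of mice on chow or HFD, and single cells from a pair of enteroid cultures. Libraries were made with the TriLink CleanTag small RNA kit, the Clontech SMARTer Ultra Low Input kit with Nextera XT, and 10x Chromium 3′ v2 chemistry, per the labels' protocols. The mice were C57BL/6J. Groups follow the titles and characteristics. For the small RNA libraries titled chow replicate 3 and HFD replicate 3, the library name gives the opposite diet, so an exchange of the 2 was an alternative.

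The authors deposited the miRNA values as RPM, where the extra letters in their file names were read as mapped to miRNAs, because each column sums to 994243 to 1000000. Each table was kept by the authors to forms over 50 RPM, which holds in at least 1 library for every Sox9, Prox1 and diet form, but only for 156 of 196 fly and 248 of 308 Lgr5 forms. Each table was normalized separately, so tests stay within a table. The authors deposited the RNA-seq values as normalized counts, that is, a signal per Ensembl gene after division by a factor per library, and whole reads were not recovered from them. The single-cell matrices are UMI counts deposited by the authors from Cell Ranger (build mm10), per the submitters' processing notes, and their header gives software version 3.0.1. The submitters' processing notes also name STAR, Salmon, DESeq2 and the builds mm9, dm3 and mm10 with no role, and the miRNA aligner is not given in the sources used here.

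For each miRNA table, log2(RPM + 1) was fitted in limma 3.58.1 (R 4.3.3) with a mean-variance trend and two-sided moderated tests, adjusted by Benjamini and Hochberg over all forms, and adjusted p < 0.05 counted as past the threshold. All 14 Sox9 libraries shared 1 fit and all 9 fly libraries another, and Prox1 and diet tables had their own. Each Sox9 fraction was compared with the mean of the other sorted fractions. For RNA-seq, log2(normalized count + 1) was fitted in the same way for the 16720 of 48440 genes with a mean of at least 10. Fold changes put the group named first over the other. Median-ratio rescaling, an alternative, divides each library by its median ratio to the geometric mean of all libraries. Exact permutation tests of 3 against 3 libraries cannot go below p = 0.1, so single features rest on limma. Replicates were not paired in the fits. In the Sox9 table mouse codes pair the libraries: after removal of fraction means, 19 of 26 pairs of libraries from 1 mouse correlated above 0.1 (median 0.36, range −0.30 to 0.84), against a median of −0.21 for the 52 other pairs. A replicate block was therefore an alternative and not part of the fit.

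Gene lists were fixed before the data were examined, as were the comparisons and most alternatives. The mouse miRNA lists are the miR-7 family, neuroendocrine miRNAs, the miR-183, miR-17-92, miR-200, miR-192 with miR-194 and miR-215, let-7, miR-30, miR-29 and miR-34 families, and injury, blood, muscle and Dlk1-Dio3 miRNAs. The fly lists are families, clusters and a stem cell and growth list, and the gene lists cover cell types, metabolism, stress and reported miR-7 targets, all recalled from general knowledge. A list takes the canonical form of every arm and gene copy of a member. List counts can therefore hold 1 mature miRNA more than once, and the list tests treat such copies as separate. Lists with at least 3 members were tested with camera at a preset correlation of 0.01 and, as a check set beforehand, with an estimated one, and fry, which asks if a list moves 1 way and compares it with no other genes, was run beside them. Of 100 list tests, 36 passed at the preset correlation and 4 with an estimated correlation; fry called 52 of 97.

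Named miRNAs are the miR-7 family, up to 10 forms per direction with the largest fold changes among those past the threshold whose groups do not overlap and whose higher group has a mean of at least 100 RPM, and up to 3 members per list. Where fewer than 10 passed, the 5 smallest p-values are given too. Named genes are up to 15 per direction with at least 50 normalized counts and up to 4 per list. For enteroids they are genes with at least 50 UMIs whose interval excludes no change, up to 10 per direction, and up to 4 per list. Where such names run past 10 the text gives their range, and some named genes are not reported here. The count of canonical and shifted forms, the lane values and the within-series values were added after the data were seen.

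Cells with at least 200 genes and at most 25% mitochondrial UMIs were kept. With 1 library per group no test of the treatment was made. UMI sums were compared with exact Poisson intervals (95%, conditional on the total), genes at 0 were set to a floor of 3 counts per library, and the median log2 ratio of list genes with at least 10 UMIs was placed among 10000 random lists matched in 20 expression bins. Clusters came from scanpy 1.11.5 (Python 3.11.15) with 2000 variable genes, 20 components, 15 neighbours and a resolution of 1.0. A cluster was named when its 50 top genes held at least 3 markers of a type and its top 10 at least 1. That last rule was set after clusters were seen, and a minimum of 2 would leave unnamed the 31 cells named by it at resolution 1.5. Cluster fold changes were first taken from summed counts, which put 9 enteroendocrine markers in the top 10 of 1 cluster, and then from means of per-cell values, which put 0 there; the second was kept because single cells rule the sums. The count of enterocyte-like cells was added later, and a minimum of 10 UMIs on alternatives per gene was tried and dropped. No doublet caller was run, and cluster sizes are given over both libraries only. The target of LNA-7 is a miRNA, which 3′ single-cell libraries do not measure.

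Alternatives set beforehand for miRNAs were a pseudocount of 10, median-ratio rescaling, a mean of at least 100 RPM, no trend, only the libraries of the contrast, each replicate left out, a replicate block, mouse series as a factor, omission of both diet libraries numbered 3, and their diets exchanged. RNA-seq added no filter, a mean of at least 50 and quantile normalization. The overlap added a threshold of 0.01, the block and at least 100 RPM. Enteroids added all barcodes, at least 500 genes, cells thinned to 1000 UMIs, mitochondrial UMIs out of the total, and resolutions of 0.5 and 1.5. Alternatives chosen after seeing the data were canonical starts with 1 form per mature miRNA, lists with shifted forms, omission of embryonic, miR-122 and 4-base-earlier forms, omission of the mouse numbered 2, sequencing lane as a factor in flies, and omission of the 2 fly libraries with the highest smallest value.

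The code was tested on simulated data in which a known set of features was changed. With 40 features changed 2-fold and 4-fold, limma found 28 and 33 in the Sox9 High design, 25 and 34 in Low, 27 and 33 in Sublow, 27 and 33 in Negative, 26 and 33 for High against Low, and 22 and 32 against non-sorted cells. It found 0 and 13 in the Prox1 design, 12 and 23 in flies at 4 h, 11 and 22 at 12 h, and 10 and 32 in the diet design. Of 200 genes in the RNA-seq design it found 51 and 134. All found features had the right sign, and at most 6 unchanged ones were called. A simulated enteroid list without a change lay above 68.2% of random lists, and with a shift of 1 log2 above 100%. Figures were drawn with matplotlib 3.10.9, and numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.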

Results

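The series holds 49 samples of gut epithelium from mice and flies, and its title asks how microRNA-7 (miR-7) bears on the enteroendocrine lineage, the hormone-secreting cells of the gut. Small RNA was sequenced from crypt cells of male Sox9-EGFP mice, a reporter line whose green fluorescence follows the crypt transcription factor Sox9. These cells were sorted into High, Low, Sublow and Negative fractions with 3 libraries each, and 2 libraries came from non-sorted cells. Small RNA was also sequenced from sorted Prox1-positive and Prox1-negative cells with 3 libraries each, Prox1 being a transcription factor of enteroendocrine and tuft cells. Another 2 small RNA libraries came from Lgr5-sorted cells, which enter no comparison. Sox9-EGFP Low crypt cells of female mice on chow (n = 4) or a high-fat diet (HFD, n = 4) gave small RNA libraries, and RNA-seq of Sox9-EGFP Low crypt cells under the same mouse codes gave another 4 and 4. Fly midguts gave 3 small RNA libraries each without challenge and at 4 h and 12 h after feeding on Ecc15, a bacterium that injures the fly gut. Single cells were sequenced from jejunal enteroids given a locked nucleic acid against miR-7 (LNA-7) or a scrambled one, with 1 library each.

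Levels are means ± SD over the libraries of a group. The miRNA values are reads scaled to all reads mapped to miRNAs (RPM) and carry no depth. Each gene copy of a miRNA, and each form that starts at another base, has its own line. Copies of 1 mature miRNA can repeat the same values, as miR-218-1-5p and miR-218-2-5p did in the Lgr5 libraries (each at 64.48 and 55.89 RPM). Counts of forms, in lists too, are therefore not counts of separate miRNAs. There were 380 forms of 178 mature miRNAs in the Sox9 libraries, 339 of 156 in the Prox1 libraries, 316 of 165 in the diet libraries and 196 of 104 in the fly libraries. The RNA-seq table is in normalized counts that sum to 15003500–18799700 per chow library and 17368500–20844300 per HFD library. The LNA-7 enteroids gave 1169872 UMIs (unique molecular identifiers) in 319 barcodes, and the scramble enteroids 1518074 in 273. Fold changes are on the scale of log2(value + 1), which understates them for features near 0. The p-values stand for animals only if the replicates of a group came from separate animals.

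The first question was which miRNAs go with the highest Sox9 reporter level, where this reporter line has most enteroendocrine cells. miR-375-3p, which shapes endocrine cells, was at 123490 ± 10093 RPM in High (n = 3). It was at 58075 ± 11881 in Low, 15413 ± 2643 in Sublow and 837 ± 256 in Negative cells (n = 3 each). miR-7b-5p followed the same order at 9772 ± 2021, 8107 ± 822, 1422 ± 367 and 50.3 ± 24.7 RPM, and so did the abundant miR-7a-1-5p at 30279 ± 5906, 25905 ± 674, 8016 ± 2136 and 2059 ± 328. miR-194-1-5p, a miRNA of absorptive cells, ran the other way at 6746 ± 435, 8614 ± 1306, 50874 ± 9033 and 109618 ± 3423 RPM.

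Against the mean of the other sorted fractions, 225 of 380 forms passed in High cells (adjusted p < 0.05, limma), 118 higher and 107 lower. The High libraries were read on lane 8 or merged with no single lane, and all Sublow and Negative ones on lane 5 or 6 alone. Lane therefore cannot be told apart from the difference of High cells to Sublow and Negative cells. The Low, Sublow and Negative contrasts below carry this limit in part. miR-375-3p was 13.8-fold higher (adjusted p = 1.33e-08), miR-182-5p 4.50-fold (adjusted p = 1e-09), miR-672-5p 23.4-fold (adjusted p = 2.92e-07) and miR-1224-5p 60.6-fold (adjusted p = 7.99e-08), each in all 3 High libraries above all 9 others. miR-7b-5p was 11.9-fold higher (adjusted p = 4.03e-07) and miR-7a-1-5p 4.02-fold (adjusted p = 6.4e-06), with High libraries overlapping Low ones. The miR-7 passenger strand miR-7a-2-3p was 18.3-fold higher without overlap (adjusted p = 1.28e-06), and so were miR-139-3p 14.7-fold, miR-125a-5p 10.3-fold, let-7e-5p 8.50-fold, and miR-92b-3p and 3 shifted forms of miR-375-3p up to 11.7-fold. The strongest decreases without overlap were in miR-215-3p (6.10-fold), miR-802-5p (5.49-fold), miR-203-3p (5.16-fold), forms of miR-194, miR-215, miR-5105 and miR-5109 (4.44- to 5.10-fold), and a form of miR-5109 listed at 0 in High cells. miR-17-5p, from a cluster that drives proliferation, was 3.82-fold lower (adjusted p = 2.28e-05), and miR-21-5p 2.65-fold lower (adjusted p = 1.21e-06), both in all 3 libraries.

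By list, 4 of the 5 miR-7 forms rose in High cells (4 adjusted over the list alone; median 2.01 log2) and 8 of the 11 neuroendocrine forms (9 adjusted over the list alone; 1 fell after rescaling). All 7 miR-200 forms rose (7 adjusted over the list alone), as did both of the miR-183 cluster. Of the miR-17-92 clusters 9 of 16 forms fell (9 adjusted over the list alone; median −0.70), of miR-192, miR-194 and miR-215 5 of 7 (5 adjusted over the list alone; median −1.99), and of the injury list 6 of 9 with 2 higher (8 adjusted over the list alone). The camera test called the neuroendocrine (adjusted p = 0.00686), miR-17-92 (0.00236), miR-200 (0.0042), miR-192, miR-194 and miR-215 (0.00143) and injury lists (0.0208). With an estimated correlation none passed (adjusted p = 0.0658 or more). The let-7 list split at 5 up and 2 down of 13, its median at 0 and its mean at 0.42, and the miR-30 list at 4 and 1 of 10. miR-34a-5p fell and miR-29a-3p did not pass. Single forms rose in the blood list (of 3) and the muscle list (of 2), where the medians were −1.17 and −0.17, and both Dlk1-Dio3 forms rose (1 after rescaling).

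In Low cells, which this reporter enriches for stem cells, 232 forms passed, 176 higher and 56 lower. Median-ratio rescaling turned this split to 65 higher and 93 lower and moved the median of all forms from 0.52 to −0.02 log2, so directions near that size depend on scaling. miR-7b-5p (9.38-fold, adjusted p = 2.78e-06), miR-7a-1-5p (3.31-fold, adjusted p = 3.38e-05) and miR-375-3p (4.97-fold, adjusted p = 2.14e-06) were higher in Low cells than in the mean of the rest, overlapping the High libraries. Without overlap, miR-181d-5p reached 1547 ± 218 RPM (4.30-fold, adjusted p = 3.11e-07), miR-92a-1-3p 14659 ± 3079 RPM (3.05-fold, adjusted p = 5.39e-05) and miR-148a-3p 8441 ± 1284 RPM (3.08-fold, adjusted p = 1.76e-05). miR-181c-3p, miR-222-3p, miR-10b-5p, miR-342-5p, miR-25-3p and 2 shifted forms of miR-92a-1-3p were 2.69- to 6.67-fold higher in the same way. miR-210-3p was 3.26-fold, miR-22-3p 2.30-fold, and forms of miR-5105 and miR-140-3p 3.45- and 1.39-fold lower in all 3 Low libraries. By list, 5 of 5 miR-7 forms rose (4 after rescaling; 5 adjusted over the list alone), 10 of 11 neuroendocrine (8 after rescaling), 10 of 16 of miR-17-92 (5 after rescaling) and 13 of 13 of let-7 (4 up and 1 down after rescaling). The miR-192, miR-194 and miR-215 forms fell in 5 and rose in 1 of 7, with camera adjusted p = 3.15e-09 and adjusted p = 0.002 with an estimated correlation, while the let-7 call (adjusted p = 0.00422) gave adjusted p = 0.529 with an estimated correlation. Directions that flip with rescaling were miR-182-5p (0.27 to −0.29 log2) and the medians of the miR-183 cluster (0.22 to −0.34), the miR-200 list (0.24 to −0.32; 3 of 7 up) and the injury list (0.16 to −0.39; 3 up and 1 down of 9). The miR-30 list rose in 5 of 10 and miR-29a-3p rose, neither after rescaling. The blood list rose in 2 of 3, the muscle list in 1 of 2, and the Dlk1-Dio3 and miR-34 lists in none.

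In Sublow cells, the reporter's progenitor fraction, 120 forms passed, 64 higher and 56 lower. miR-215-5p was at 243442 ± 9384 RPM, 2.80-fold above the mean of the rest (adjusted p = 1.34e-06), and miR-194-1-5p 2.72-fold (adjusted p = 4.08e-06), both below the Negative cells in all 3 libraries. miR-21-5p at 36398 ± 2768 RPM (1.89-fold, adjusted p = 0.000249) and miR-185-5p at 206 ± 15.3 RPM (1.93-fold, adjusted p = 0.000174) were higher than in every other sorted library, as were 2 shifted forms of miR-21-5p (1.77- and 1.89-fold), let-7g-5p (1.37-fold) and a form of miR-192-5p (1.28-fold). No miR-7 form passed, with miR-7a-1-5p at −0.58 log2 (adjusted p = 0.0595) and miR-7b-5p at −0.16 (adjusted p = 0.718). By list, 5 of 7 miR-192, miR-194 and miR-215 forms rose, with camera adjusted p = 0.000649 and adjusted p = 0.0495 with an estimated correlation. The injury list rose in 5 of 9, the miR-17-92 list in 4 of 16, and the let-7 list in 7 of 13 with 3 lower (median 0.26, mean −0.04). The neuroendocrine list fell in 3 of 11, the miR-200 list in 3 of 7, both miR-183 cluster forms fell, and the miR-30 list had 1 up and 2 down of 10. miR-34a-5p rose, and no form of the miR-29, blood, muscle or Dlk1-Dio3 lists passed.

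In Negative cells, the differentiated fraction, 292 forms passed, 87 higher and 205 lower, a split that rescaling turned to 116 and 114 as it moved the median of all forms from −0.71 to −0.09 log2. miR-7b-5p fell 99.8-fold (adjusted p = 1.35e-09), miR-375-3p 58.5-fold (adjusted p = 4.44e-10), miR-7a-1-5p 8.92-fold (adjusted p = 8.29e-08), miR-1224-5p 96.9-fold, miR-184-3p 109-fold and miR-7a-2-3p more than that, in all 3 libraries against all 9 others. miR-92b-3p and 4 shifted forms of miR-7b-5p and miR-375-3p were 28.4- to 76.0-fold lower. miR-194-1-5p rose 7.69-fold (adjusted p = 9.33e-10), miR-215-5p 4.37-fold (adjusted p = 3.09e-09) and miR-215-3p 7.64-fold (adjusted p = 3.6e-10) in the same libraries. miR-5109 was at 2388 ± 493 RPM (10.4-fold, adjusted p = 2.87e-08, limma). In addition, 9 forms of miR-5102, miR-5105, miR-5109, miR-5115 and miR-194 were 11.6- to 19.3-fold higher. In the Lgr5 libraries miR-5105 and miR-5109 were listed at starts from 8 bases earlier to 8 later. There miR-5109 was at 33.4 and 126.9 RPM, below its form 3 bases later at 78.5 and 235.4. Whether such forms are miRNAs was not tested, here or in the other comparisons. By list, all 5 miR-7 forms and all 11 neuroendocrine forms fell (9 after rescaling), as did all 13 of let-7 (10 after rescaling, 1 up) and all 7 of miR-200 (5 after rescaling). The miR-192, miR-194 and miR-215 list rose in 5 and fell in 1 of 7 (7 up after rescaling), with camera adjusted p = 1.54e-07 and adjusted p = 0.00464 with an estimated correlation. The camera calls of the neuroendocrine (0.0101), let-7 (0.00575) and injury lists (0.00851; 5 up and 2 down of 9, median 0.38, mean −0.03) gave adjusted p = 0.213 or more with an estimated correlation. The miR-17-92 list had 5 of 16 lower, yet 5 higher and 1 lower after rescaling, and the miR-30 list 8 of 10 lower, yet 2 up and 2 down after rescaling. miR-29a-3p fell (0.15 log2 higher, not past, after rescaling), miR-34a-5p passed as higher only after rescaling, both miR-183 cluster and both Dlk1-Dio3 forms fell (the latter not after rescaling), and the blood and muscle lists had 1 lower form each.

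High and Low cells were set against each other to ask what parts them. Of 131 forms past the threshold 38 were higher in High and 93 lower, and rescaling turned this to 72 and 51 (median of all forms −0.19 to 0.17 log2). miR-182-5p was 2.69-fold higher in High cells (36206 ± 3107 against 13456 ± 976 RPM, adjusted p = 9.92e-07) and miR-375-3p 2.15-fold (adjusted p = 0.00326). miR-672-5p was 10.1-fold (adjusted p = 8.37e-05) and miR-210-3p, which responds to low oxygen, 7.59-fold higher (113 ± 12.3 against 14.2 ± 3.44 RPM, adjusted p = 9.63e-06). miR-17-5p, miR-20a-5p, miR-92a-1-3p, miR-92a-2-3p, miR-152-3p, miR-181b-1-5p, miR-181c-3p and miR-222-3p were 3.47- to 9.95-fold lower. All of these miRNAs separated the 3 High from the 3 Low libraries, a split that chance gives to 10% of features and that 180 forms showed. miR-7a-1-5p (0.21 log2, adjusted p = 0.604) and miR-7b-5p (0.25, adjusted p = 0.616) did not pass. By list, 10 of 16 miR-17-92 forms fell (10 adjusted over the list alone; camera adjusted p = 0.00778, adjusted p = 0.352 with an estimated correlation), and 5 of 7 miR-200 forms rose (7 after rescaling; camera adjusted p = 0.00142, adjusted p = 0.145 with an estimated correlation). The neuroendocrine list had 4 up and 2 down of 11, the let-7 list 1 up and 8 down of 13 (3 up and 2 down after rescaling), the miR-30 list 2 down of 10 (1 up after rescaling), and the injury list 5 down of 9 (1 up and 4 down after rescaling). miR-215-3p alone of the miR-192, miR-194 and miR-215 list, miR-29a-3p and 1 muscle form fell, none after rescaling, while miR-34a-5p fell and both miR-183 cluster forms rose; no blood or Dlk1-Dio3 form passed.

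Against non-sorted crypt cells (n = 2), taken as the unselected background, 245 forms passed. Of these 144 were higher and 101 lower, or 103 and 110 after rescaling (median of all forms 0.47 to 0.04 log2). Both non-sorted libraries were read on lane 6 alone. The High libraries were read on lane 8 (replicate 3) or merged (replicates 1 and 2), so lane and sorting cannot be told apart here either. miR-375-3p was 12.4-fold (adjusted p = 3.05e-07), miR-7b-5p 6.85-fold (adjusted p = 5.1e-05) and miR-7a-1-5p 4.85-fold higher in High cells (adjusted p = 3.65e-05), and miR-215-5p 8.49-fold lower (adjusted p = 5.94e-09), without overlap. miR-1224-5p was 54.6-fold higher, and let-7e-5p, miR-125a-5p, miR-184-3p, miR-672-5p, miR-7a-2-3p, forms of miR-10a-5p and a shifted form of miR-375-3p 11.3- to 23.1-fold. miR-5115 at 11060 ± 6825 RPM in non-sorted cells was 75.1-fold lower in High cells (adjusted p = 0.00091), and shifted forms of miR-5115, miR-5109 and miR-194-1-5p were 29.0- to 144-fold lower or listed at 0. By list, all 5 miR-7, 9 of 11 neuroendocrine, 7 of 7 miR-200 (6 after rescaling), 11 of 13 let-7 (4 up and 1 down after rescaling) and 6 of 10 miR-30 forms (3 up and 1 down after rescaling) rose. The miR-192, miR-194 and miR-215 list fell in 5 of 7, with camera adjusted p = 6.72e-06 and adjusted p = 0.012 with an estimated correlation. The neuroendocrine (0.0226), let-7 (0.0226), miR-200 (0.0117), miR-17-92 (0.00931; 1 up and 5 down of 16, 6 down after rescaling) and injury calls (0.0155; 2 up and 6 down of 9) gave adjusted p = 0.186 or more with an estimated correlation. Both miR-183 cluster forms and 1 form each of the blood and muscle lists rose, miR-34a-5p fell, and no miR-29 or Dlk1-Dio3 form passed. Without a call, the camera direction was opposite to the list median for the miR-200 and injury lists in Low, the blood list in High and Sublow, and the miR-17-92 list in Negative cells.

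Prox1-positive cells were compared with Prox1-negative cells to see which miRNAs mark them (n = 3 each). miR-375-3p was at 114091 ± 59790 RPM in positive and 5529 ± 2082 in negative cells, 19.3-fold higher (adjusted p = 0.000753), and miR-182-5p 11.7-fold higher (35191 ± 18950 against 2776 ± 328 RPM, adjusted p = 0.000519). miR-7b-5p was 8.71-fold higher (2039 ± 1577 against 216 ± 143 RPM, adjusted p = 0.00658), in all 3 libraries above all 3. miR-7a-1-5p was 3.73-fold higher (7759 ± 5511 against 1928 ± 1131 RPM, adjusted p = 0.0292), with overlap. miR-672-5p at 282 ± 76.5 RPM (adjusted p = 0.00014) and miR-1224-5p at 377 ± 260 RPM (adjusted p = 0.000519) were listed at 0 in all negative libraries, as were 4 shifted forms of miR-5108 and miR-5119. let-7e-5p (26.0-fold), miR-744-5p (27.1-fold), miR-574-5p (39.1-fold), miR-139-3p (66.7-fold) and miR-5119 (146-fold) were higher without overlap. miR-194-1-5p fell 5.89-fold (21163 ± 7488 against 120377 ± 16563 RPM, adjusted p = 0.000753), miR-21-5p 4.47-fold (3156 ± 362 against 15024 ± 6549 RPM, adjusted p = 0.00242), and miR-17-5p, miR-215-3p, miR-29c-3p, miR-378-5p, miR-802-5p and forms of miR-194 5.85- to 12.2-fold, all without overlap.

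**Figure D1:**
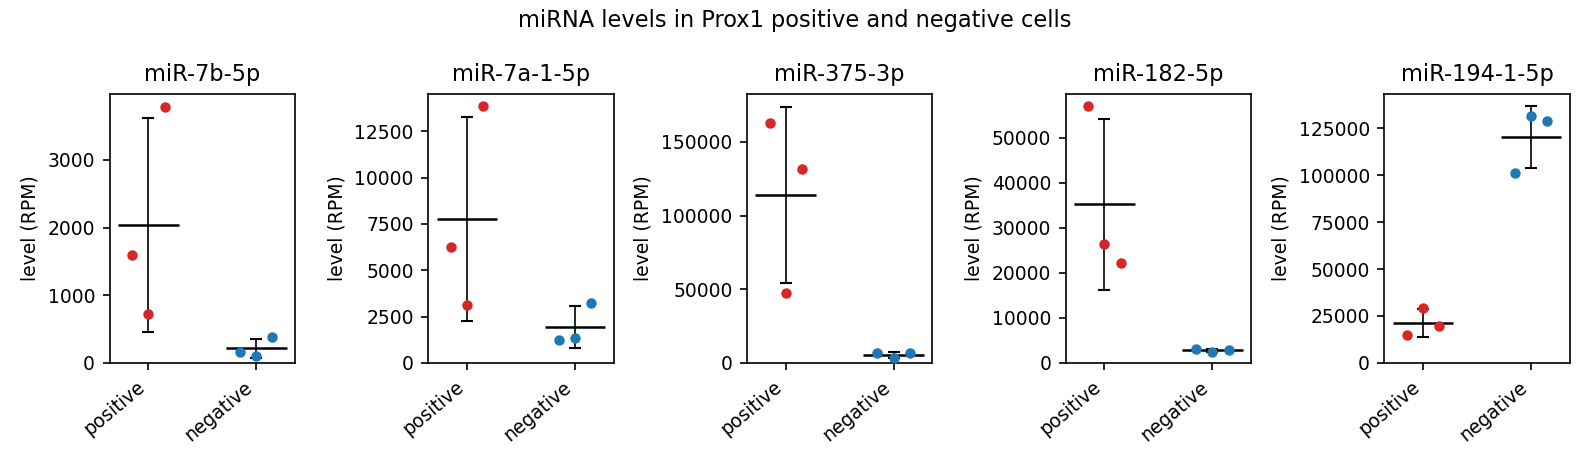
Level in RPM (linear axis) of the same 5 miRNAs in Prox1-positive and Prox1-negative cells; points are libraries, lines group means and bars SD (n = 3 each). miR-375-3p stands at 114091 RPM in positive and 5529 RPM in negative cells, and miR-194-1-5p at 21163 and 120377.

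In total 173 of 339 forms passed, 90 higher and 83 lower in Prox1-positive cells, and 202 did not overlap, where chance gives 10%. Leaving out negative replicate 2 left 84 and negative replicate 3 left 102, and rescaling gave 95 higher and 66 lower. By list, 4 of 5 miR-7 forms rose (5 past adjusted over the list alone), 7 of 9 neuroendocrine (7 adjusted over the list alone), 8 of 13 let-7 (9 adjusted over the list alone) and both miR-183 cluster forms, while 2 of 8 miR-200 forms rose. Lower were 9 of 14 miR-17-92 (11 adjusted over the list alone), 5 of 8 miR-192, miR-194 and miR-215 (6 adjusted over the list alone), 4 of 8 miR-30 and both miR-29 forms, and the injury list had 1 up and 4 down of 8 (2 up and 3 down after rescaling). The camera test called the neuroendocrine, miR-192, miR-194 and miR-215 and let-7 lists (each adjusted p = 0.00377; adjusted p = 0.461 with an estimated correlation) and the miR-17-92 list (adjusted p = 0.0148; adjusted p = 0.462 with an estimated correlation). miR-342-5p of the blood list rose, and no miR-34 or muscle form passed.

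To ask whether Sox9 High and Prox1-positive cells share their miRNAs, the 283 forms in both tables were compared. Of the 93 higher in High and the 66 higher in Prox1-positive cells, 52 were the same forms, where chance gives 21.7 (odds ratio 15.7, 95% interval 7.73–33.9, two-sided Fisher exact p = 8.06e-19). Shared forms include miR-375-3p, miR-7b-5p, miR-7a-1-5p, miR-182-5p and miR-672-5p. Of the 99 and 71 lower forms 49 were shared (24.8 by chance), and 2 forms higher in High cells were lower in Prox1-positive cells. Forms of a miRNA are not independent, and with 1 per mature miRNA 31 of 55 and 40 were shared among 136 (16.2 by chance, odds ratio 10.1, Fisher exact p = 2.21e-08).

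The diet comparison asked which miRNAs of female Sox9 Low cells change on HFD (n = 4 each). miR-375-3p was at 25406 ± 8201 RPM after HFD and 78615 ± 47452 on chow, 2.84-fold lower without overlap (adjusted p = 0.0212). miR-7b-5p was 2.05-fold lower (4402 ± 1546 against 8925 ± 3571 RPM), also without overlap, but did not pass (adjusted p = 0.0531), nor did miR-7a-1-5p at −0.53 log2 (18963 ± 4655 against 28146 ± 11510 RPM, adjusted p = 0.191). miR-146a-5p, a brake on inflammatory signalling, fell 6.15-fold (179 ± 101 against 1073 ± 641 RPM, adjusted p = 0.00767), miR-10a-5p 3.04-fold (267 ± 165 against 720 ± 115 RPM, adjusted p = 0.0135) and miR-191-5p 1.83-fold (11872 ± 1046 against 22102 ± 4941 RPM, adjusted p = 0.0161). miR-1224-5p, miR-139-3p, miR-92b-3p, miR-181c-5p and shifted forms of miR-10a-5p and miR-375-3p were 2.04- to 6.20-fold lower, all without overlap. The largest of these, miR-1224-5p, was at −1.88 against −2.63 log2 and did not pass (adjusted p = 0.11) without chow replicate 3. miR-218-1-5p rose 4.62-fold (149 ± 29.0 against 32.1 ± 10.4 RPM, adjusted p = 0.00177), and miR-34a-5p, a target of p53, 3.14-fold (207 ± 112 against 74.0 ± 51.4 RPM, adjusted p = 0.0484), the latter not after rescaling.

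**Figure D2:**
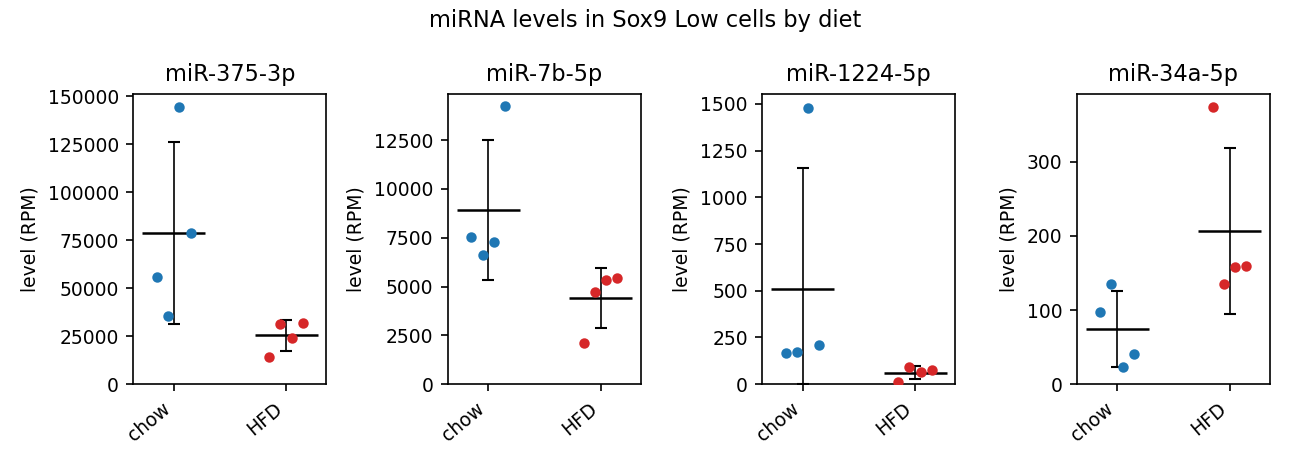
Level in RPM (linear axis) of miR-375-3p, miR-7b-5p, miR-1224-5p and miR-34a-5p in Sox9 Low cells on chow and HFD; points are libraries (n = 4 each), lines group means and bars SD, the lower bar of miR-1224-5p on chow ending at 0 because its SD of 649 exceeds its mean of 507. miR-375-3p stands at 78615 RPM on chow and 25406 RPM on HFD, and miR-34a-5p, which did not pass after rescaling, at 74.0 and 207.

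In total 66 of 316 forms passed, 49 higher and 17 lower after HFD, or 40 and 29 after rescaling (median of all forms 0.19 to −0.04 log2). Without overlap were 86 forms, where chance gives 2.86%. Leaving out 1 library gave 33 (without HFD replicate 1) to 75 forms past the threshold (without chow replicate 2). Of the 49 higher forms 36 were shifted and 13 canonical, among them shifted forms of let-7g-5p (5.52-fold), miR-92a-1-3p (5.16-fold), miR-26a, miR-30d-5p, miR-194-2-5p and miR-7a (3.65- to 4.51-fold). With canonical starts only and 1 form per mature miRNA, 1 of 157 passed (miR-218-2-5p, adjusted p = 0.00335; 62 at an unadjusted threshold of 0.05). That setting removed shifted forms and further forms of 1 mature miRNA together, so which of them ended the other calls was not separated. miR-375-3p then had adjusted p = 0.0526, and it missed the threshold without HFD replicate 1 (0.066), chow replicate 3 (0.0749), HFD replicate 3 (0.0515) or chow replicate 4 (0.0522), with 0.00591 to 0.139 over these and other alternatives and 0.997 with the diets of the libraries numbered 3 exchanged. miR-7b-5p passed after rescaling (−1.27 log2, adjusted p = 0.0259), with mouse series as a factor (0.0273), at a mean of at least 100 RPM (0.0493) and without chow replicate 2 (0.0445). Within the mouse series BC18 and BC24, miR-375-3p changed by −1.07 and −1.94 log2, miR-7b-5p by −1.16 and −0.92, miR-146a-5p by −3.43 and −1.81, and miR-218-1-5p by 1.73 and 2.68. All titled chow libraries ran on lane 1 and no HFD library did, so lane and diet cannot be told apart.

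By list, no miR-7 form passed (2 adjusted over the list alone; 2 fell after rescaling). The neuroendocrine list had 2 up and 3 down of 10 (7 adjusted over the list alone), or 2 up and 5 down after rescaling. The miR-218 forms, which are gene copies of 1 mature miRNA, were higher, and miR-375-3p and miR-1224-5p lower. The miR-17-92 list rose in 2 of 17 (1 after rescaling; 0 adjusted over the list alone), with camera adjusted p = 0.00843 and adjusted p = 0.914 with an estimated correlation. The miR-183 cluster had 0 of 2 past (2 adjusted over the list alone, both lower; 2 after rescaling). miR-194-1-5p rose alone in its list of 7 (not after rescaling), let-7d-3p fell in its list of 13 (2 after rescaling), miR-10b-5p fell in the muscle list, and miR-127-3p in the Dlk1-Dio3 list. The injury list had miR-34a-5p up and miR-146a-5p down of 9. None of 8 miR-200 (1 down after rescaling; median 0.07, mean −0.10), 10 miR-30, or the single miR-29 and blood forms passed.

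RNA-seq of Sox9 Low cells asked which genes the diet changes (n = 4 each). Acot1, an acyl-CoA thioesterase, rose 4.03-fold (2031 ± 548 against 494 ± 81.3 normalized counts, adjusted p = 0.0188), and the beta-oxidation enzyme Acadvl 2.20-fold (6365 ± 1252 against 2858 ± 310, adjusted p = 0.0333). The MHC class II gene H2-Aa fell 49.1-fold (115 ± 57.9 against 7672 ± 6114, adjusted p = 0.0333) and its invariant chain Cd74 17.8-fold (2056 ± 942 against 44624 ± 29945, adjusted p = 0.0333). Rfx6, a transcription factor of enteroendocrine cells, fell 3.99-fold (305.3 ± 115 against 1224 ± 538, adjusted p = 0.0419). The tuft cell genes Avil fell 5.29-fold (924 ± 450 against 4511 ± 1283, adjusted p = 0.0333) and Pou2f3 3.26-fold (318 ± 124 against 974 ± 108, adjusted p = 0.0353). None of these genes overlapped between the diets.

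In total 135 of 16720 genes passed, 25 higher and 110 lower, none with overlap, among 2476 genes without overlap where chance gives 2.86%. The smallest adjusted p was 0.0188. Of the higher genes Acaa2, Acot2, Ces2g, Clca4a, Gkn3, Mme, Hist1h1b and Dhrs4 were named by size or list, and of the lower ones H2-Ab1, H2-Eb1, H2-DMb1, Gbp2, Gbp8, Nos2, Ccl5, Afp, Map1a, Rac2, Cartpt, Parp8, Etv1, Adcy5, Il17rb and Plcg2. Cck (7160 ± 2517 against 41290 ± 32778, adjusted p = 0.0542), Reg4 (8091 ± 3971 against 45456 ± 33984, adjusted p = 0.0532) of the enteroendocrine list, Pax6, a reported miR-7 target also in that list (−2.07 log2, adjusted p = 0.0635), and Fabp1 (2.75 log2, adjusted p = 0.0546) did not pass. All 4 passed with mouse series as a factor (1392 genes in total) and with a replicate block (377). Omission of 1 library moved the count: none was left without chow replicate 1 (H2-Aa −5.70 against −5.62 log2 and Acot1 1.96 against 2.01, both adjusted p = 0.0808), HFD replicate 3, chow replicate 4 or HFD replicate 4, 1 without HFD replicate 2, 38 without HFD replicate 1, 71 without chow replicate 3 and 2509 without chow replicate 2. H2-Aa ranged from −5.12 log2 without chow replicate 2 to −6.42 without chow replicate 3. Within BC18 and BC24, Acot1 changed by 1.77 and 2.25 log2, H2-Aa by −6.91 and −4.33 and Rfx6 by −1.84 and −2.15.

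By list, PPAR targets rose in 7 of 29 and fell in none (21 past adjusted over the list alone, 20 of them higher; median 0.71, 0.89 in BC18 and 0.62 in BC24). Enteroendocrine markers fell in 1 of 34 (31 adjusted over the list alone, all lower; median −1.93, −1.64 and −2.18). Tuft markers fell in 9 of 19 (18 adjusted over the list alone; median −2.25, −3.03 and −1.38), and MHC class II genes in 5 of 8 (7 adjusted over the list alone; median −4.01, −4.93 and −2.97). Cell cycle genes had 0 of 27 past (19 adjusted over the list alone, higher; median 0.62), and immediate early genes 0 of 19 (13 adjusted over the list alone, lower; median −0.80). The camera test called these 6 lists at adjusted p = 1.33e-09 or less (MHC class II the largest); with an estimated correlation none passed (adjusted p = 0.213 or more). The fry test, which compares a list with no other genes, called PPAR targets (adjusted p = 0.0124), enteroendocrine (0.0407), tuft, MHC class II (both 0.014), immune and immediate early genes (both 0.0179) and reported miR-7 targets (0.0407), but not cell cycle genes (0.0955). Antimicrobial genes fell in 1 of 12 (camera adjusted p = 0.00327, and adjusted p = 0.276 with an estimated correlation). Goblet markers had none of 15 past, with a median of 0.73 (1.24 in BC18 and −0.08 in BC24). Their camera direction was up (adjusted p = 0.0483, and adjusted p = 0.789 with an estimated correlation). Stem cell markers had none of 18 past (median 0.03, mean 0.02, camera direction down at adjusted p = 0.909), enterocyte markers none of 25 (median 1.35 in BC18, −0.25 in BC24), and immune markers 1 of 11 lower. No gene passed among 23 of cholesterol synthesis, 16 of fatty acid synthesis (median 0.17, mean 0.02), 15 Paneth, 4 stromal, 13 insulin and IGF genes, or 19 reported miR-7 targets (5 adjusted over the list alone, 1 up and 4 down; median −0.12).

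**Figure D3:**
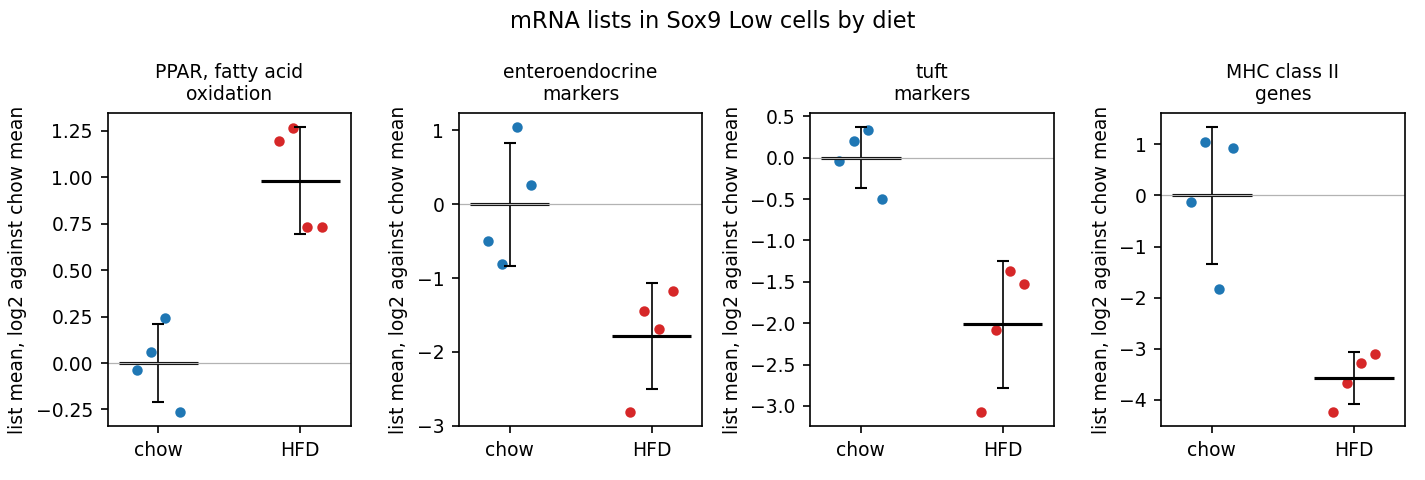
Mean level of the PPAR, enteroendocrine, tuft and MHC class II lists in each RNA-seq library of Sox9 Low cells, in log2 against the chow mean; points are libraries (n = 4 each), lines group means and bars SD. The list medians over genes are 0.71, −1.93, −2.25 and −4.01 log2 after HFD.

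In flies the question was how midgut miRNAs respond to Ecc15 (n = 3 each). At 4 h, miR-8-5p was at 2286 ± 206 against 810 ± 106 RPM without challenge, 2.83-fold higher (adjusted p = 0.00189, limma). It is the scarcer arm of miR-8, a gene that limits gut stem cell growth. The abundant arm miR-8-3p was at 26007 ± 6270 against 21580 ± 3172 RPM and did not pass. miR-277-5p rose 3.83-fold (760 ± 115 against 196 ± 13.2 RPM, adjusted p = 0.0149), miR-305-3p 2.14-fold (2871 ± 676 against 1317 ± 68.5 RPM, adjusted p = 0.0164) and a shifted form of miR-996-5p 2.24-fold (714 ± 96.8 against 321 ± 64.3 RPM, adjusted p = 0.0164). The 4 forms given as higher were the only ones of 196 past the threshold. Their groups did not overlap, which 27 forms showed and chance gives to 10%. Of the other arms, miR-277-3p was at 9131 ± 1407 against 6746 ± 1203 RPM and miR-305-5p at 2173 ± 633 against 1568 ± 199. miR-996-3p was at 338 ± 107 against 240 ± 19.5 RPM, and none of these other arms passed. At 12 h 1 form passed, miR-8-5p at 1877 ± 229 RPM (2.32-fold, adjusted p = 0.00752), and miR-305-3p and miR-277-5p (both adjusted p = 0.0531), the miR-996-5p form (0.0538) and miR-263a-3p (0.0802) came next. miR-7-5p was at 1223 ± 290 RPM without challenge, 1158 ± 397 at 4 h (adjusted p = 1.00) and 678 ± 63.5 at 12 h (−0.83 log2, adjusted p = 0.256). Its list holds 1 form, so adjustment over the list changes nothing. At 12 h it passed only an unadjusted threshold of 0.05, as 22 of 196 forms did in all. Between 12 h and 4 h none passed by limma (10 at an unadjusted threshold of 0.05; smallest adjusted p = 0.681, miR-1012-3p, miR-275-3p, miR-184-3p and miR-31a-5p first). With sequencing lane as a factor 1 form passed at 4 h and 0 at 12 h (25 at an unadjusted threshold of 0.05), and omission of single libraries gave 1 (without unchallenged replicate 1 or 3) to 6 forms at 4 h and 0 (without 12 h replicate 1) to 4 at 12 h.

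**Figure D4:**
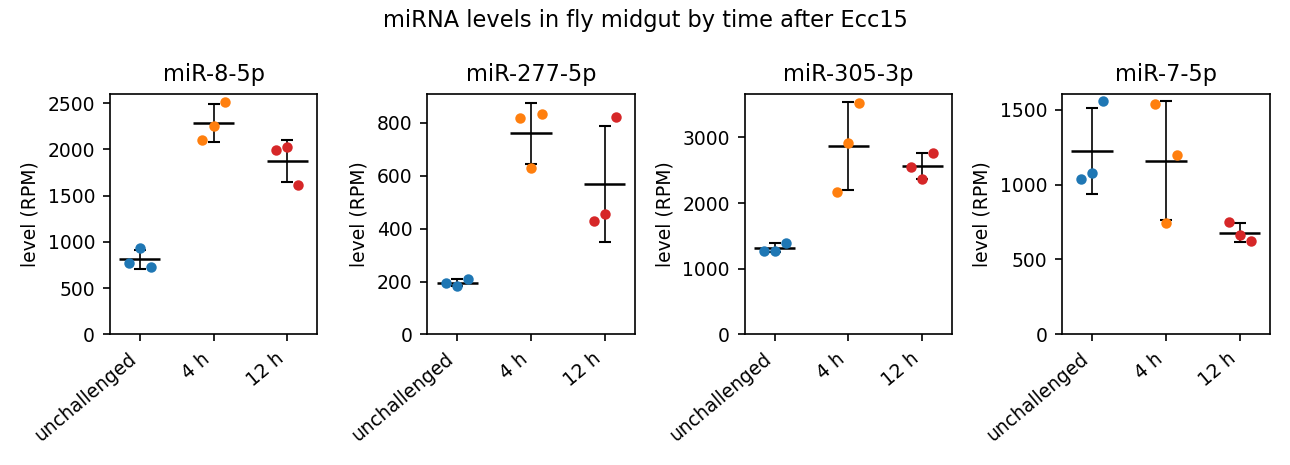
Level in RPM (linear axis) of miR-8-5p, miR-277-5p, miR-305-3p and miR-7-5p in fly midguts without challenge and at 4 h and 12 h after Ecc15; points are libraries (n = 3 each), lines group means and bars SD. miR-8-5p goes from 810 to 2286 and 1877 RPM, and miR-7-5p, which did not pass, from 1223 to 1158 and 678.

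By list, the stem cell and growth list had 2 of 14 forms higher at 4 h and 1 at 12 h (4 adjusted over the list alone at each time), with camera adjusted p = 0.00282 and 0.00234, and adjusted p = 0.159 and 0.15 with an estimated correlation. The let-7 complex had 0 of 4 past at 4 h (median −2.69; miR-100-5p and miR-125-3p listed at 0 in all 4 h libraries and in unchallenged replicate 2), with camera adjusted p = 0.0181 and adjusted p = 0.325 with an estimated correlation. Its abundant member let-7-5p was at 8151 ± 2269 against 12231 ± 4708 RPM (−0.55 log2, adjusted p = 0.818). The cluster of miR-277, miR-317 and miR-34 and that of miR-275 and miR-305 had 1 form each past at 4 h and none at 12 h. No form of the miR-310, miR-2, miR-9, miR-306, miR-279, miR-276, miR-263, miR-959 or muscle and nerve lists passed at either time. At 12 h against 4 h no list had a form past, and miR-7-5p passed only an unadjusted threshold of 0.05. There median and mean differ in sign for the growth list (−0.20 and 0.05) and the let-7 complex (−0.08 and 0.81). The same holds for the miR-277 (0.01 and −0.10) and miR-275 clusters (−0.02 and 0.18). Median and mean also differ in sign for the miR-306 cluster at 4 h (−0.09 and 0.44) and the miR-2 family at 12 h (0.02 and −0.03).

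The enteroid libraries asked what blocking miR-7 changes, with no replicates and so no test of the treatment. Intervals and floors below cover counting error only. Random lists do not share a cell type as marker lists do, so extreme ranks can come from the mix of cells caught. Such ranks are therefore no test of the treatment either. Goblet and Paneth markers too lay at extremes, above 0.05% and 99.83% of random lists. After filters 92 of 319 LNA-7 barcodes (28.8%) and 140 of 273 scramble barcodes (51.3%) were kept. Too few genes were found in 198 and 75 barcodes. Over all barcodes the median was 42 and 573 genes, and the median mitochondrial share was 97.7% and 17.8%. Kept cells held 761696 and 1096968 UMIs. Enterocyte markers made up less of the UMIs with LNA-7 (−0.55 log2; median gene −0.58, below all of 10000 matched random lists), with 0 genes higher and 24 lower. Stem cell markers made up more (0.48 log2; median 0.52, above 99.97% of random lists), with 10 genes higher and 4 lower. Immediate early genes (−0.55, median −0.61; 2 higher and 14 lower) and PPAR targets (−0.41, median −0.32; 4 and 22) were lower.

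Enteroendocrine markers summed to more UMIs with LNA-7 (0.61 log2, exact interval 0.57–0.65), but their median gene was lower (−0.51 over 28 genes, below all of 10000 matched random lists; 8 higher and 20 lower), so sum and median differ in sign. With all barcodes the sum's ratio was 0.46, and with cells thinned to 1000 UMIs −0.82. The hormone counts rest on single cells: in 1 cell lay 99.8% of the 4052 LNA-7 and 95.1% of the 920 scramble UMIs of Cck (2.67 log2), and 99.8% of 1239 and 100% of 248 UMIs of Gcg (2.85 log2). Gip had 1166 against 0 UMIs (at least 560-fold higher against a floor of 3 counts per library; 98.8% in 1 cell), and Sct 2447 against 78 (5.50 log2; 83.1% in 1 LNA-7 cell). Nts had 0 against 4719 UMIs (at least 1092-fold lower; 99.8% in 1 cell), Tac1 0 against 284 (at least 65.7-fold lower; 99.3% in 1 cell), Ghrl 4 against 601 (−6.70 log2; 98.3% in 1 scramble cell) and Chgb 52 against 566 (−2.92 log2; 73.9% in 1 scramble cell). Of the other genes with the largest ratios, Tff1, Msln, Serpinb9b, Akr1b8 and Ccl20 were higher with 87.5% or more of their LNA-7 UMIs in 1 cell, and Afp and Bex2 were lower with 96.6% or more of their scramble UMIs in 1 cell. Reg1, less concentrated, had 50 against 611 UMIs (−3.08 log2; 32.4% in 1 scramble cell), and Nphs1 54 against 13 (2.58 log2).

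Goblet markers (1.00 log2, median −0.55), antimicrobial genes (−0.23, median 0.18) and reported miR-7 targets (0.06, median −0.03; 6 higher and 8 lower) differ in sign between sum and median. Paneth (0.18, median 0.29) and cell cycle genes (0.14, median 0.05) turned to −0.27 and −0.0211 with all barcodes. Tuft markers were at −0.74 (median −1.52), cholesterol synthesis at −0.01 (median 0.05), fatty acid synthesis at 0.29 (median 0.16) and insulin and IGF genes at −0.19 (median −0.02). Stromal (9 against 13 UMIs), MHC class II (3 against 15) and immune genes (1 against 30) were too sparse for a median. Clustering put the 232 cells in 7 clusters: cycling-like 51 cells (22.0%, Clopper-Pearson 95% interval 16.8–27.9%), enterocyte-like 106 in 3 clusters (45.7%, 39.2–52.3%), Paneth-like 6 (2.59%, 0.955–5.54%) and 69 unnamed in 2 (29.7%, 23.9–36.1%). No cluster was enteroendocrine-like at resolutions 1.0 and 0.5. At both, 1 unnamed cluster of 32 cells held 9 markers of its best-matching type among its 50 top genes but 0 among its top 10. The top-10 rule, set after clusters were seen, left it without a name. At resolution 1.5, 31 cells got the enteroendocrine-like name. Of their 10 top genes 1 is a marker, Chgb, most of whose scramble UMIs lie in 1 cell, and most others are mitochondrial or nuclear RNAs, so the name is weak.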

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

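The tests of lane, exchanged diets, embryonic miRNAs and enteroendocrine cell numbers were chosen after the results were seen. Those of canonical forms, chow replicate 3, scaling and other splits were marked as set before. The patterns weighed with canonical forms, chow replicate 3 and scaling were themselves found in these results.

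In the diet libraries, 36 shifted miRNA forms were higher after HFD, with a median of 1.79 log2. Their canonical partners had a median of 0.21 log2. The shifted forms were selected as higher in these same data and the partners were not, so the difference of the medians decides nothing. Taken alone, the partners changed little as a set, with 3 of 30 distinct ones past the threshold as higher. An exchange of the diets of the mice numbered 3 is argued against by RNA-seq. There the PPAR list mean of chow replicate 3 against the lowest HFD library was −0.49 log2. RNA-seq cannot show an exchange of only the 2 small RNA libraries, whose names hold the conflict, so that stays open. The median ratio of shifted to canonical form over 129 pairs was higher in every library off lane 1 than in every library on it (gap of 0.67 log2). The share of all RPM in shifted forms overlapped, at 4.64% to 6.35% in HFD and 4.69% to 5.71% in chow libraries. All titled chow libraries ran on lane 1, so lane and diet cannot be told apart. An effect of diet on miRNA processing stays open and was not tested.

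Embryonic stem cell miRNAs, 10 forms in all, summed to 1523–3422 RPM in some Sox9 libraries and were at 0 in others. The sum was over 50 RPM in 5 of 5 libraries read on lane 6 alone and at 0 in 5 of 5 on other single lanes (two-sided Fisher exact p = 0.00794), and merged libraries had 2 of each. All 4 sorted fractions held both kinds, and so did 1 mouse, which argues against a property of fraction or mouse. Carry-over from another library on lane 6 may be the source, as a hypothesis.

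Lower miR-375-3p and miR-7b-5p after HFD were weighed against fewer enteroendocrine cells in the sorted fraction, since the median of the enteroendocrine mRNA list was lower too (1 of 34 genes past; adjusted p = 0.274 for the list with an estimated correlation). Over the 8 mice, centred on each diet's mean, miR-7b-5p and the list mean had r = 0.62 (exact permutation p = 0.104, adjusted p = 0.156; Spearman rho 0.52, exact permutation p = 0.219), and r = −0.01 without HFD replicate 1 and chow replicate 2, so that relation rests on those samples and decides nothing. For miR-375-3p r was 0.98 (exact permutation p = 0.00174, adjusted p = 0.00521; rho 0.98, exact permutation p = 0.00174; 0.97 without 2 mice), and for miR-7a-1-5p 0.45 (exact permutation p = 0.337; rho 0.38), so fewer such cells may account for miR-375-3p. The centring took out diet but not mouse series. The list mean of chow mice was 1.04 and 0.27 in BC24 and −0.50 and −0.81 in BC18. In HFD mice it was −1.69 and −1.18 in BC24 and −2.81 and −1.45 in BC18. A difference between the series shared by both measures was thus not separated from r. Chow replicate 3 as the sole cause is argued against, since without it miR-375-3p was still at −1.15 log2 against −1.51, though it no longer passed (adjusted p = 0.0749). Scaling as the sole cause is argued against as well, since rescaling gave −1.74 log2, while lane, which follows diet in these libraries, stays open.

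A library far from the other 3 of its group was found in 23 of 294 groups tested (7.82%), where chance gives about 1 in 20, or 14.7. The measure is the gap of that library divided by the range of its group. Chow replicate 4 was high in miR-7a-1-5p (0.853), miR-7b-5p (0.833) and the shifted forms of miR-7a-1-5p (0.855) and miR-7a-2-5p (0.842). Chow replicate 3 was high in miR-1224-5p (0.902), Cartpt (0.879) and Cyp3a11 (0.889) and low in miR-203-3p (0.899) and Spink4 (0.861). Chow replicate 2 was high in Aurkb (0.837) and low in Btg2 (0.894) and Acly (0.905). HFD replicate 1 was high in miR-34a-5p (0.839) and low in miR-7b-5p (0.844), Etv1 (0.881), Cck (0.962), Irs1 (0.860) and the mean of the reported miR-7 targets (0.976). HFD replicate 2 was high in Gzma (1, as the other 3 were equal) and Cyp3a11 (0.935) and low in miR-203-3p (0.922). HFD replicate 3 was high in Sox9 (0.880) and HFD replicate 4 in Pdgfra (0.913).

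Other splits of the same libraries were counted for every comparison. For High 1 of 100 splits, the real one, gave as many calls (225, highest other 146). It was 1 of 100 for Low (232, highest other 136) and for Negative (292, highest other 240). The other splits mix libraries of all sorted fractions, so the differences between fractions widen the spread within their groups. The shares therefore argue only against sorted fractions that are all alike. They single out no contrast and do not exclude chance. For Sublow it was 4 of 100 (120; highest other 175) and 3 other splits called more. Among the splits that part as many pairs of libraries from 1 mouse, the highest others were 132 for High, 3 for Low, 129 for Sublow and 240 for Negative. For Sublow that is over the real count, so the argument against chance is weaker there. For the diets 1 of 35 splits gave as many miRNA forms (66, highest other 0) and 1 of 35 as many genes (135, highest other 1). That is the smallest share that 35 splits can give, so it argues against chance but does not exclude it. In the small RNA libraries the real split also follows lane. The split by mouse series gave 0 in both. In designs of 10 splits a share under 0.05 cannot be had: High against Low gave 131 (highest other 3), Prox1 173 (0), flies 4 at 4 h (2), 1 at 12 h (1; 3 splits as many) and 0 between the times (1; 10 as many).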

How the results depend on the processing

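Of the alternatives below, canonical forms, lane and fly library omission were chosen after the results were seen; the estimated correlation was set beforehand as a check in the design. Of 9284 values, 8470 were counted as unchanged, 644 lost the threshold, 163 gained it and 7 reversed. A change of direction counted as reversed only where the value passed the threshold before or after it. The 8470 can therefore hold values that changed direction without passing in either setting. Of 330 enteroid values beside the enteroendocrine marker sum 258 stayed within their interval, 63 moved and 9 reversed. Unless a cause is named, the cause was not tested.

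With fewer forms tested, a mean of at least 100 RPM gave 141 calls in High, 147 in Low, 166 in Negative, 151 against non-sorted cells and 113 for Prox1, but 8 in flies at 4 h and 7 at 12 h. Canonical starts with 1 form per mature miRNA gave 107 in High, 108 in Low, 65 in Sublow, 121 in Negative, 73 for High against Low, 97 against non-sorted cells, 89 for Prox1, 7 and 3 in flies at 4 h and 12 h, and 1 for the diets. In flies at 4 h, lane as a factor gave 1 and omission of 12 h replicate 2 and 4 h replicate 3 gave 2. At 12 h, lane gave 0 by limma (25 at an unadjusted 0.05), that omission 5 and only the contrast's libraries 6; between the times the omission gave 1. Without both libraries numbered 3 the diets gave 30 forms and 13 genes, and with their diets exchanged 0 forms (8 unadjusted) and 0 genes (405 unadjusted). For genes a pseudocount of 10 gave 212, no filter 399, a mean of at least 50 gave 230 and mouse series as a factor 1392. List tests fell from 36 to 4 with an estimated correlation.

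The replicate block gave 236 in High, 236 in Low, 130 in Sublow, 296 in Negative, 144 for High against Low and 248 against non-sorted cells, within 1.5 times the counts reported. In the other tables libraries share only a number: correlations over 0.1 within a number held for 2 of 3 Prox1, 3 of 9 fly, 1 of 4 diet miRNA and 2 of 4 diet RNA-seq pairs. There the block gave 168 for Prox1, 6 and 4 in flies at 4 h and 12 h, 0 between the times (18 unadjusted), 78 forms and 377 genes for the diets, and 38 list tests, and miR-7b-5p passed (adjusted p = 0.0357).

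Leaving out 1 library gave 216–230 in High, 198–235 in Low, 85–138 in Sublow, 258–303 in Negative, 108–140 for High against Low and 211–253 against non-sorted cells. Prox1 gave 84–187, with 84 without negative replicate 2 and 102 without negative replicate 3. Flies at 4 h gave 1–6, with 1 without unchallenged replicate 1 or 3 and 2 without 4 h replicate 3. At 12 h they gave 0–4, with 0 (25 unadjusted) without 12 h replicate 1 and 4 without 4 h replicate 3, and 8 of 9 omissions moved the count. Between the times they gave 0–2, with 2 without 12 h replicate 2 and 1 without 12 h replicate 3. Diet forms gave 33–75, with 33 without HFD replicate 1 and 36 without HFD replicate 4. Diet genes gave 0–2509: 0 without chow replicate 1 (3808 unadjusted), chow replicate 4, HFD replicate 3 or HFD replicate 4, then 1 without HFD replicate 2, 38 without HFD replicate 1, 71 without chow replicate 3 and 2509 without chow replicate 2. The overlap's odds ratio was 9.67–37.1 under omissions, 29.7 at a threshold of 0.01, 17.9 with the block and 14.3 with at least 100 RPM.

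Rescaling, which shifts all forms of a library alike, reversed miR-182-5p (−0.29 log2), miR-183-5p (−0.38), miR-200b-3p (−0.25) and miR-200c-3p (−0.0712) in Low and miR-29a-3p (0.15) and miR-30a-5p (0.0101) in Negative cells. With diets exchanged miR-106b-5p went to −0.0043. In the enteroids the marker sum was 0.46 with all barcodes and −0.82 with cells thinned, where single rich cells weigh less. Paneth markers went to −0.27 and −0.17 in the same settings and cell cycle genes to −0.0211 with all barcodes. Thinned, Gcg went to −0.10, Akr1b8 to −0.38, Nupr1 to 0.73 and Fyb to 0.62, and Gm15284 went to −0.53 with all barcodes and −0.62 thinned. Not run were a count test, since whole reads were not recovered, and contrast-only fits for Prox1 and the diets, whose tables hold no other groups. RPM tables give no depth, and UMI depth limits the enteroid genes named with a floor.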

Other observations

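The correlation tests and the miRNAs singled out here were chosen after the results were seen. Sox9 Low cells of mice on HFD had lower levels of miR-375-3p together with lower Rfx6 and a lower median of 34 enteroendocrine genes (−1.93 log2), of 19 tuft genes (−2.25) and of 8 MHC class II genes (−4.01), beside higher fatty acid oxidation genes. Past the threshold were 1 of the 34, 9 of the 19, 5 of the 8 and 7 of 29 fatty acid oxidation genes. No such list passed with an estimated correlation (adjusted p = 0.213 or more), though fry, which compares them with no other genes, called them (adjusted p = 0.0407 or less). Omission of any of 4 single libraries left 0 genes. Immediate early genes had a median of −0.80 with 0 of 19 past. The mean of 11 immune markers was lower in every HFD library (−0.56 to −1.16) than in every chow library (−0.23 to 0.21). Their median change was only −0.25 log2, with 8 lower and 3 higher, and camera did not call them (adjusted p = 0.0853). In both mouse series the list medians had the same sign. Within the diets miR-375-3p went with the enteroendocrine list (r = 0.98, with mouse series not taken out). A hypothesis is therefore that the HFD fraction held fewer hormone-secreting cells. A test on miR-7b-5p left this open (r = 0.62, exact permutation p = 0.104), and lane and diet of the small RNA libraries cannot be told apart.

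Most miR-7 forms did not set High cells apart from Low ones. miR-7a-1-5p and miR-7b-5p differed by 0.21 and 0.25 log2 between High and Low cells and did not pass. The scarcer miR-7a-2-3p was above every Low library in High cells but did not pass either (0.73 log2, adjusted p = 0.237), while miR-375-3p, miR-182-5p, miR-672-5p and miR-1224-5p were 2.15-fold or more higher in High than in Low. miR-210-3p was lowest in Low cells, at 14.2 ± 3.44 RPM (n = 3), against 113 ± 12.3 in High cells.

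The 2 Lgr5-sorted libraries, which enter no comparison and were normalized apart, had miR-7a-1-5p at 1569 and 1247 RPM, miR-7b-5p at 53.4 and 53, miR-375-3p at 20943 and 18945, miR-182-5p at 10076 and 10809, miR-192-5p at 308211 and 298490, miR-215-5p at 55475 and 62986 and let-7b-5p at 83646 and 90366. miR-122, a liver miRNA, was at 114–633 RPM in the 4 merged Sox9 libraries and lower in all others, down to 5.08 RPM. In the fly table the smallest value above 0 was 107.73 RPM in 4 h replicate 3 and 83.16 in 12 h replicate 2, against 37.98–50.17 in the other libraries.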
